A study of Homo sapiens with 2 samples.

How the data were processed

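Total RNA of PANC-1 cells was measured on 1-colour Agilent human miRNA arrays (design 070156), with 1 array for cells treated with 100 µM rapamycin and 1 array for control cells. Groups were taken from the titles, the agent and the group letters of the labels. The source name of the control sample also says rapamycin, while its title, agent, letter and treatment protocol say control, and the latter were followed. The labels name a whole-transcript cRNA kit for the labelling although the arrays carry miRNA probes, and how the miRNAs were labelled is not stated otherwise. The labels give neither a treatment time nor a vehicle, and the unit of the dose cannot be checked from the files. The rapamycin and the control array lie on different slides, so slide and treatment cannot be told apart.

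Per the file headers, the images were read with Agilent Feature Extraction 10.7.1.1, and the deposited spot values are intensity values in arbitrary units, with the local background subtracted and a spatial trend removed for each spot. Per the file headers, no normalization between arrays was applied to these intensities. The headers name hg19 as the genome build of the probe positions. The authors also deposited a table of log2 values with 1 value per probe and array. The submitters' processing notes name limma without a version or a role, and how that table was normalised is not stated. Its columns had medians of 2.54 with rapamycin and 2.54 in the control, its lowest value was 1.97 in both, and its values had a Spearman correlation of 0.918 (rapamycin) and 0.922 (control) with the spot intensities of detected spots. Whether that table was centred or floored beyond this is unknown, and it was used only as an alternative.

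Each array holds 53144 features, of which 50980 are spots of 5893 probes for 2549 human miRNAs and 2164 are control spots. Spots marked as outliers by the image software were left out, 2049 with rapamycin and 1686 in the control, and 0 spots were saturated. The log2 of the background-subtracted intensity was averaged over the spots of a probe, after a floor of 1 on the scaled intensity. Each array was scaled by its 75th percentile over the 895 probes detected on both arrays, which was 131 with rapamycin and 147 in the control and gave factors of 1.06 and 0.944. A probe was detected where at least 50% of its spots were marked as well above background, and a miRNA where at least 1 probe was. The difference of a miRNA is the mean over its probes detected on both arrays of rapamycin minus control, in log2. Its standard error over spots had a median of 0.05. For the 346 miRNAs with 2 such probes, the differences of the 2 probes had a Pearson correlation of 0.750 and a Spearman correlation of 0.692 across miRNAs. For a miRNA detected on 1 array, the lower bound of the fold sets its signal against the lowest detected probe of the other array or its own signal there, whichever was higher. No error over spots was taken off, and where its own signal was higher the bound is the measured difference. The lowest detected probe stood at 3.53 with rapamycin and 3.49 in the control.

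With 1 array per group no test was run and no p-value is given, and the number of arrays limits the precision. The following choices were made before the data were examined. They are the settings above, 24 lists of miRNAs (families and clusters, miRNAs reported to target autophagy genes or MTOR, cancer and tissue markers, and array-specific groups), 2 classes by registry number, most of the alternatives, and the rule for named miRNAs. The rule took the 12 largest differences in each direction among miRNAs whose probes all differed the same way. The difference as scaled also had to exceed 2 standard errors over spots. The rule further took the 5 largest bounds in each direction. It also took the 10 brightest miRNAs, and from each list the 2 brightest and the highest and lowest members. A few further list members were named after their values were seen, among them miR-17-5p, miR-92a-3p, miR-99b-5p, miR-376a-3p, miR-320c, miR-1202 and miR-7107-5p. Of the 260 listed names 255 are on the array, and 148 different listed miRNAs were detected on both arrays. A list with at least 3 members detected on both arrays has a median. Its percentile among 10000 random lists of the same size, matched on mean signal in 10 classes, describes these 2 arrays alone. Giving differences relative to the median of all miRNAs was decided after the data were examined, since some scalings moved that median by more than 0.1. Gene names around precursors come from the GRCh38.p14 gene table, matched by precursor name, without coordinates.

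The alternatives changed the scaling (75th percentile over all probes, quantile normalization, median, or none), the background (normexp with an offset of 50) and the summary (total gene signal of the image software, or the brightest probe). They also changed the values (the authors' table), the detection rule, the filter on dim probes and the fold threshold (1.5 and 4). Scaling to 4 fly spike-in features, and keeping only miRNAs with at least 2 probes, were added after the data were examined. The steps were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. They were tested on simulated data for this comparison with 514 miRNAs, of which 200 were given log2 differences of 1.5 or 2. There, 100% of the altered miRNAs passed the 2-fold threshold at each size, and 0% of the 314 others did, after the median of the others was subtracted. These sizes lay beyond the threshold and only noise between spots was simulated. The test therefore checks the steps, and does not bear on differences as small as those found here.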

Results

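MicroRNA (miRNA) levels were measured in PANC-1, an established cell line from a human pancreatic carcinoma, on 1 array of cells given rapamycin and 1 array of control cells kept in culture medium. The dose is 100 µM as the labels give it, high for this drug, and the files offer no check of that unit. Rapamycin inhibits the kinase complex mTORC1, which holds back autophagy in well-fed cells, and the labels describe the treated cells as the group in which autophagy was induced. The comparison asks which miRNAs differed between cells with and without rapamycin. On the rapamycin array, 18.1% of the miRNA spots lay well above background, against 17.8% on the control array. Of the 2549 human miRNAs on the array, 506 (19.9%) were detected with rapamycin and 514 (20.2%) in the control. Both arrays detected 489 miRNAs, only the rapamycin array detected 17, only the control array detected 25, and neither detected 2018. With 1 array per group no difference has a replicate check and none was tested. Each ± value is a standard error over the spots of a miRNA, which covers the error within an array alone.

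The miRNA profile of the rapamycin-treated cells lay close to that of the control cells. The largest difference upward was that of miR-5787, whose normalised log2 signal was 7.49 with rapamycin and 6.50 in the control, 1.98-fold higher. The largest difference downward was that of miR-3907, at 3.56 with rapamycin and 4.52 in the control, 1.93-fold lower. Among the 489 miRNAs detected on both arrays, 0 were at least 2-fold higher and 0 at least 2-fold lower. At a threshold of 1.5-fold, 4 miRNAs (miR-5787, miR-664b-5p, miR-4270 and miR-6785-5p) were higher and 2 (miR-3907 and miR-4261) were lower. The signals of the 2 arrays had a Pearson correlation of 0.996 and a Spearman correlation of 0.986 across miRNAs, which are not independent replicates. The median log2 difference of all 489 miRNAs, rapamycin minus control, was −0.05 and ranged from −0.21 to 0.07 under the alternative settings. Of the 13 alternatives, 4 only shift all miRNAs alike, so relative differences and percentiles can differ in the other 9 alone. From here on, each difference is therefore given relative to the median of all miRNAs. On that scale 1 miRNA, miR-5787, was at least 2-fold higher and 0 were at least 2-fold lower. At 1.5-fold, 5 were higher on that scale, miR-630 joining the 4 above, and 1 was lower, miR-3907. The central 95% of the miRNAs lay between −0.33 and 0.38. The standard deviation of the differences was 0.18, against 0.08 from the error over spots alone. It was 0.09 with the normexp background, under which 53 of the 73 named miRNAs moved outside their 95% interval over spots and 5 reversed. The offset of 50 in that setting pulls the log2 differences of dim miRNAs toward 0 by construction. The standard deviation was 0.42 with the total gene signal of the image software. There, 65 of the 73 stayed within their 95% interval over spots. Across all miRNAs, however, its differences had a Pearson correlation of 0.399 with the reported ones, the lowest of the 13 alternatives.

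**Figure D1:**
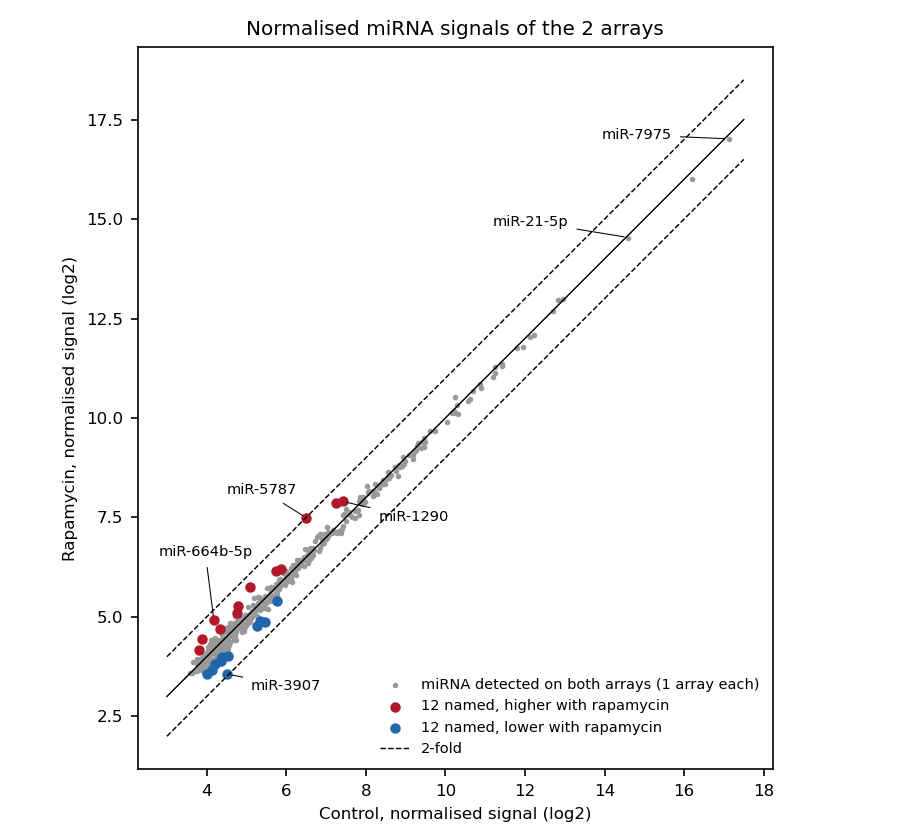
Normalised log2 signal of each of the 489 miRNAs detected on both arrays, rapamycin on the vertical axis against control on the horizontal axis. Each point is 1 miRNA, the solid line marks equal signals, the dashed lines mark a 2-fold difference, and colours mark the 12 named miRNAs higher with rapamycin and the 12 lower. All points lie inside the 2-fold lines, with miR-5787 and miR-3907 closest to them.

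The largest differences are named among miRNAs whose probes all differed the same way and whose difference as scaled exceeded 2 standard errors over spots. A miRNA with 1 probe detected on both arrays meets the first part of this rule in advance. The 12 miRNAs with the largest difference upward under this rule were led by miR-5787, at 1.03 ± 0.02 relative to all miRNAs, or 2.05-fold. The next was miR-664b-5p, at 0.79 ± 0.09, whose probe target lies on chromosome X from 153996879 to 153996894 in hg19. The GRCh38.p14 gene table places its precursor gene MIR664B within the spans of DKC1, which encodes the pseudouridine synthase dyskerin, and of the small nucleolar RNA gene SNORA36A. The difference was 0.69 ± 0.04 for miR-4270 and 0.65 ± 0.02 for miR-6785-5p. It was 0.62 ± 0.09 for miR-630, a miRNA reported to target autophagy genes. It was 0.53 ± 0.02 for miR-1290, whose sequence resembles a stretch of a small nuclear RNA, and 0.39 ± 0.09 for miR-503-5p of the miR-15/16 family. The others were miR-4697-5p (0.52), miR-6124 (0.44), miR-328-5p (0.41), miR-188-5p (0.39) and miR-1207-5p (0.38). Of the 12, miR-664b-5p, miR-630, miR-1290, miR-4697-5p and miR-328-5p had 1 probe detected on both arrays. None of these 12 changed sign in an alternative setting that measured it, but their sizes depended on the setting. The smallest difference under the alternatives was 0.63 for miR-5787, 0.22 for miR-664b-5p, 0.17 for miR-630 and 0.11 for miR-503-5p. That of miR-328-5p ranged from 0.11 to 3.82, the latter with the total gene signal. Which miRNAs ranked highest depended on the setting too. Of the 12 largest differences upward by size alone, 10 stayed among the 12 largest with quantile normalization and 9 with the normexp background. The count was 6 with the total gene signal, 2 with no filter on dim probes and 6 in the authors' table. It was 7 where only miRNAs with at least 2 probes were kept.

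The 12 miRNAs with the largest difference downward under the same rule were led by miR-3907, at −0.91 ± 0.20, and miR-4261, at −0.56 ± 0.08. Of the 12, only miR-4261, miR-154-3p and miR-6723-5p had more than 1 probe detected on both arrays. The rule left out miR-423-3p, at −0.42 ± 0.31. The difference of miR-7-5p, a miRNA abundant in islet and neural cells, was −0.43 ± 0.10, from a log2 signal of 5.26 in the control to 4.78 with rapamycin, and turned to 0.07 with the total gene signal of the image software. The difference was −0.41 ± 0.07 for miR-154-3p and −0.33 ± 0.05 for miR-376b-3p. Both belong to the imprinted DLK1-DIO3 cluster, with probe targets on chromosome 14 in hg19 from 101526145 to 101526163 and from 101506837 to 101506855. It was −0.47 ± 0.16 for miR-193b-5p, with its probe target on chromosome 16 from 14397847 to 14397858. It was −0.41 ± 0.11 for miR-4521, which turned to 0.03 with the total gene signal and to 0.005 with no filter on dim probes. The others were miR-6723-5p (−0.40), miR-6813-3p (−0.39), miR-219a-5p (−0.38), miR-500a-5p (−0.37) and miR-516a-5p (−0.33). The sizes of these also depended on the setting, with miR-3907 between −0.95 and −0.15 and miR-376b-3p between −0.39 and −0.15. Several of the 12 were dim: with rapamycin, miR-3907 stood at 3.56 and miR-219a-5p at 3.57, where the lowest detected probe stood at 3.53. By size alone, without the rule, the 12 largest downward held miR-423-3p in place of miR-376b-3p. Of those 12, 11 stayed among the 12 largest with quantile normalization and 9 with the brightest probe. The count was 1 with the normexp background, 4 with the total gene signal and 4 in the authors' table. It was 0 where only miRNAs above the median signal were kept, and 3 where only miRNAs with at least 2 probes were.

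The 10 brightest miRNAs differed little. The difference of miR-21-5p, a miRNA raised in many carcinomas, was −0.02 ± 0.01, at log2 signals of 14.54 with rapamycin and 14.60 in the control, and was above 0 with quantile normalization and in the authors' table. Its probe target lies on chromosome 17 from 57918637 to 57918655 in hg19, and the GRCh38.p14 gene table places MIR21 within the span of VMP1, which encodes a membrane protein needed for autophagosome formation. The difference was 0.17 ± 0.01 for miR-494-3p, the highest of the 10. It was −0.13 ± 0.01 for both miR-7977 and miR-5100, and that of miR-7977 turned to 0.11 with quantile normalization and to 0.08 in the authors' table. It was −0.07 ± 0.02 for miR-7975, −0.09 ± 0.02 for let-7a-5p, −0.05 ± 0.03 for miR-29a-3p and −0.01 ± 0.01 for miR-23a-3p, all 4 of which were above 0 with quantile normalization and in the authors' table. It was 0.07 ± 0.01 for miR-7641 and 0.02 ± 0.01 for miR-8069, both of which were below 0 with the normexp background, the latter also with no filter on dim probes.

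The miRNAs reported to target autophagy genes lay on both sides of the other miRNAs. Of 23 listed, 16 were detected on both arrays, 7 above and 9 below the median of all miRNAs. They ranged from −0.43 for miR-7-5p to 0.62 for miR-630. By more than 2 standard errors over spots, 2 of the 16 were higher and 7 lower, against 113 and 112 of all 489 miRNAs. The median of the list was −0.03, turned to 0.02 with quantile normalization or in the authors' table, and lay at percentile 25.8 of 10000 random lists matched on signal. With the normexp background it was −0.10 and lay at percentile 1.36, and in the other alternatives the percentile stayed within the central 95%, up to 55.0. miR-30a-5p, reported to repress the autophagy gene BECN1, was at 0.01 ± 0.02, with the other sign under the normexp background and with no filter on dim probes. Within the list miR-376a-3p was at −0.11 ± 0.02, miR-17-5p at 0.12 ± 0.03 and miR-101-3p at 0.08 ± 0.06, the last with the other sign in the authors' table. The miRNAs reported to target MTOR or its pathway had a median of −0.11, with 5 of the 6 measured below the median of all miRNAs. The list median ranged from −0.15 to −0.02 under the alternatives. It lay at percentile 2.22 of its random lists, and between 0.32 and 24.6 under the alternatives, outside the central 95% in 2 of the 9 that can differ. Of these 6 miRNAs, 3 (miR-99a-5p, miR-99b-5p and miR-100-5p) also stand in the miR-99/100 and miR-125 list.

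Members of the miR-99/100 and miR-125 families were lower on the rapamycin array. All 5 lay below the median of all miRNAs, 3 by more than 2 standard errors over spots, as did 112 of all 489 miRNAs. The median of the list was −0.10, at percentile 2.29 of random lists, and −0.02 in the authors' table. The percentile ranged from 0.295 to 7.63 under the alternatives, outside the central 95% in 5 of the 9. The difference was −0.20 ± 0.03 for miR-125a-5p and −0.12 ± 0.03 for miR-99b-5p. It was −0.10 ± 0.02 for miR-100-5p, which reached 0.002 with quantile normalization, and −0.03 ± 0.02 for miR-125b-5p, above 0 with quantile normalization and in the authors' table. In the let-7 family, 7 of 9 members were lower and the median was −0.08, at percentile 3.80 of random lists and between 0.795 and 4.20 under the alternatives, outside the central 95% in 5 of the 9. With quantile normalization that median was −0.007. The difference was −0.17 ± 0.03 for let-7e-5p and 0.13 ± 0.02 for let-7c-5p. It was −0.08 ± 0.02 for let-7f-5p, which was above 0 with quantile normalization and in the authors' table. Probes of such closely related sequences can bind one another's targets, so the values of single let-7, miR-17, miR-320 and miR-99/100 members are uncertain.

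The other miRNA families lay within the range of random lists. The miR-15/16 family had a median of −0.07 (percentile 12.4), with 6 of 7 members lower and miR-503-5p higher. The miR-17-92 cluster and its paralogous clusters had a median of 0.03 (percentile 82.8), which turned to −0.04 with the normexp background. Of the 11 measured members, 8 were higher, with miR-18a-5p at 0.18 ± 0.05 and miR-92a-3p at 0.13 ± 0.02, and 3 were lower. The miR-30 family had a median of 0.01 (percentile 57.3), with the other sign in 4 alternatives (quantile normalization, normexp background, brightest probe and no filter on dim probes). The miR-29 family had a median of 0.03 (percentile 79.4), which was −0.06 with the normexp background. The miR-23/27/24 clusters had a median of −0.01 (percentile 57.8) and the miR-181, miR-26, miR-103, miR-107, miR-130 and miR-301 families one of −0.03 (percentile 27.4), both above 0 with quantile normalization and in the authors' table.

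**Figure D2:**
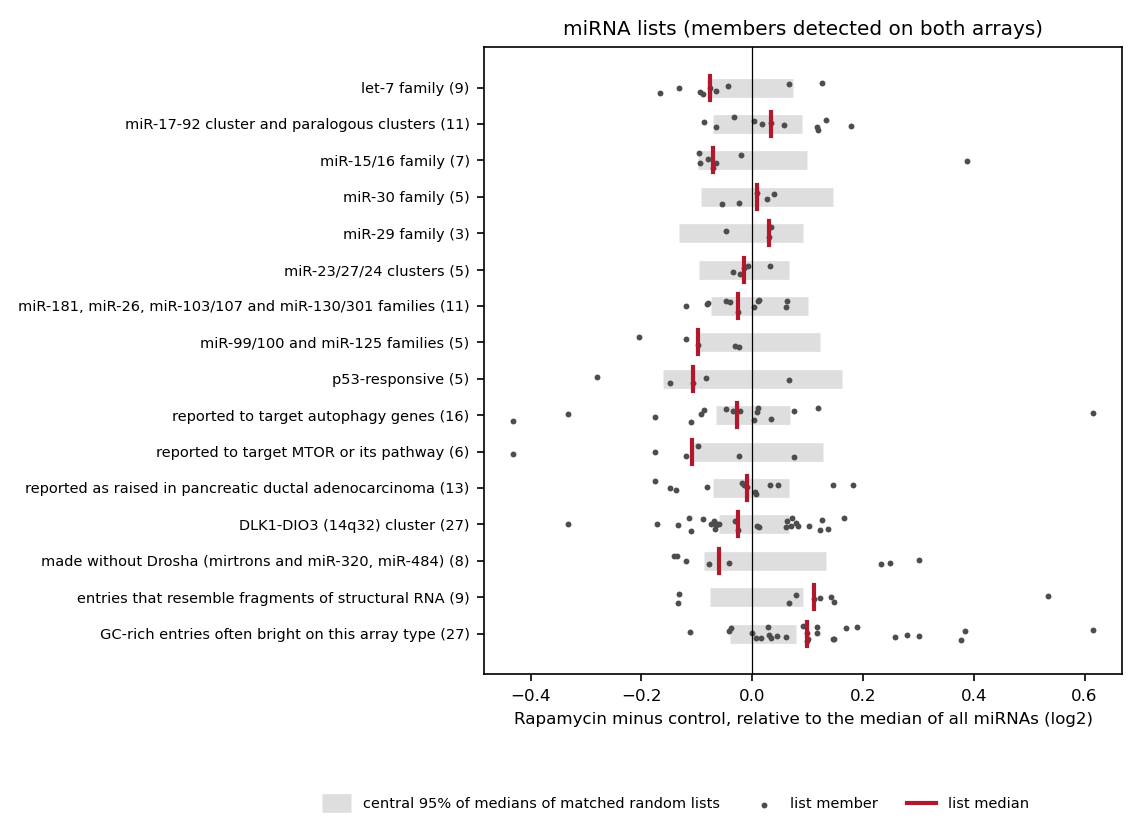
Difference between the arrays for each member of 16 miRNA lists, as log2 of rapamycin minus control relative to the median of all 489 miRNAs. Points are miRNAs detected on both arrays (number in brackets), red bars are list medians and grey bands are the central 95% of the medians of 10000 random lists matched on signal. The GC-rich and structural RNA medians lie above the band and the miR-99/100 and MTOR medians at its lower edge (percentiles 2.29 and 2.22). Under the alternatives, the medians of the miR-17-92, miR-30, miR-29, miR-23/27/24, miR-181, autophagy, adenocarcinoma and Drosha lists change sign at least once.

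miRNAs reported as raised in pancreatic ductal adenocarcinoma were evenly divided. Of 13 measured, 6 were higher and 7 lower, and their median was −0.01 (percentile 50.1), above 0 with quantile normalization and in the authors' table. The difference was 0.18 ± 0.03 for miR-221-3p. It was −0.18 ± 0.17 for miR-155-5p, −1.81 with the total gene signal, and above 0 with the normexp background and in the authors' table. The hypoxia-responsive miR-210-3p was at −0.14 ± 0.04, and miR-210-5p was detected on neither array. The p53-responsive list had a median of −0.11 (percentile 10.6), with 4 of 5 members lower, among them miR-192-5p at −0.28 ± 0.04 and miR-34a-5p at −0.08 ± 0.03. In the DLK1-DIO3 cluster, 27 of 31 members were detected on both arrays, 13 above and 14 below the median of all miRNAs. Their median was −0.03 (percentile 18.0), and its percentile ranged from 0.90 to 70.3 under the alternatives.

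miRNAs typical of particular cell types, those of epithelial and pancreatic cells included, were mostly at background. The miR-200 family, typical of epithelial cells, was detected for 0 of its 5 members on either array. The stromal and smooth-muscle list, with miR-143-3p and miR-145-5p, was detected for 0 of 8. Among 8 blood cell miRNAs, 1 was detected on both arrays, miR-486-5p at 0.04 ± 0.10. Among 8 miRNAs of skeletal muscle, liver and neurons, 2 were detected. miR-9-5p was at 0.12 ± 0.05, with the other sign in the authors' table, and miR-128-3p at 0.01 ± 0.03, with the other sign in 6 alternatives. Of 7 acinar and islet miRNAs, miR-7-5p was detected on both arrays, miR-148a-3p on the rapamycin array alone, and 5 on neither. The signal of miR-148a-3p was 1.08-fold that on the control array, a measured difference with no error over spots taken off. The chromosome 19 cluster was detected on both arrays for 1 of 20 members on the array, miR-516a-5p. The miR-302 and miR-371 to miR-373 clusters were detected for 1 of 9, miR-371a-5p at −0.02 ± 0.11, with the other sign in 3 alternatives.

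GC-rich miRNA entries, many of them registered late and bright on this type of array, were slightly higher with rapamycin. Of 27 measured, 24 lay above the median of all miRNAs. By more than 2 standard errors over spots, 16 of the 27 were higher, against 113 of all 489 miRNAs. The median of the list was 0.10, with an order-statistic 95% interval of 0.03 to 0.17, and lay at percentile 99.8 of random lists matched on signal. Among random lists matched on the GC content of the probes it lay at percentile 91.3, inside their central 95%. The difference was 0.38 ± 0.03 for miR-1207-5p, 0.38 ± 0.04 for miR-7107-5p, 0.28 ± 0.03 for miR-1202 and −0.11 ± 0.04 for miR-7114-5p. The highest member, miR-630 at 0.62, was dim, with a mean log2 signal of 4.16. Its probe GC content was 52.9%, below the median of 58.1% over all miRNAs. The signal-matched percentile was between 99.3 and 99.9 in the 9 alternatives that do more than shift all miRNAs alike, while the median itself was 0.03 with the normexp background. Across the 489 miRNAs, the difference had a Spearman correlation of 0.226 with the GC content of the probes and 0.124 with the signal. Entries that resemble fragments of structural RNA had a median of 0.11 (percentile 99.1, and 92.6 to 99.7 under the alternatives), with an order-statistic 95% interval of −0.13 to 0.15 that includes 0. That median was 0.01 with the normexp background. Of these 9, 7 were higher and 2 lower, namely miR-7977 and miR-5100. The miRNAs made without Drosha had a median of −0.06 (percentile 7.62), which was 0.02 with no filter on dim probes. In that list 3 of 8 were higher, among them miR-1225-5p at 0.30 ± 0.03 and miR-320c at 0.23 ± 0.07, and 5 were lower, among them miR-320b at −0.14 ± 0.02. The difference was 0.15 for miR-1225-5p with the normexp background, and 0.002 for miR-320c where every spot had to be well above background. Of the 16 lists with a median, 4 lay outside the central 95% of random lists matched on signal. Chance gives 0.8 for lists of unrelated miRNAs without shared members. Family members whose probes bind one another's targets are not unrelated, so 0.8 may be too low here. The 4 lists outside are also not independent, since the miR-99/100 and MTOR lists share 3 miRNAs and the GC-rich and structural RNA lists share 1 (miR-3960), and the GC-rich list lay inside when matched on GC. The 219 let-7 and miRNA entries with registry numbers up to 600 had a median difference of −0.07 as scaled, not set against the median of all miRNAs, and the 238 entries numbered 1200 or above one of −0.002.

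**Figure D3:**
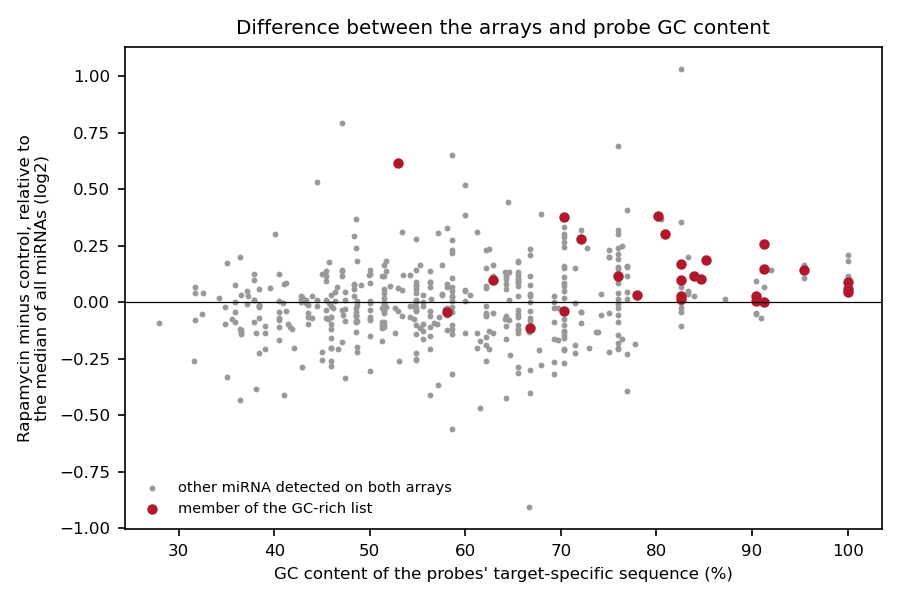
Difference between the arrays of each of the 489 miRNAs, as log2 of rapamycin minus control relative to the median of all miRNAs, against the GC content in percent of the target-specific sequence of its probes. Red points are the 27 measured members of the GC-rich list, of which 24 lie above 0, and grey points are the other miRNAs.

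miRNAs detected on only 1 array were dim. The highest lower bound of a fold was that of miR-146b-5p, detected in the control alone and at least 1.56-fold lower with rapamycin. The bounds for the next control miRNAs were at least 1.37-fold for miR-378d, 1.36-fold for miR-485-3p, and 1.28-fold for miR-1237-3p and for miR-6760-3p. On the rapamycin array alone, miR-5703 was at least 1.49-fold higher, miR-718 1.42-fold, miR-615-3p 1.35-fold and miR-2392 1.30-fold. For miR-4446-3p the value of 1.26-fold is the measured difference, as its own control signal stood above the lowest detected probe. The median bound was 1.21-fold for the 25 control miRNAs and 1.11-fold for the 17 rapamycin miRNAs, of which 14 had a bound above 1. All these bounds leave out the error over spots, so the folds could be smaller.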

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

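The control feature hur_4, which the files do not describe further, differed by 0.128 ± 0.01 (log2, rapamycin minus control) on the 2 arrays, a signal outside the miRNA measurement that was well above background on both. The other bright control features of its series were lower, at −0.09 for hur_1, −0.05 for hur_2, −0.27 for hur_5 and −0.19 for hur_6. All these values are as scaled, where the median of all miRNAs was −0.05, so hur_2 lay close to that median. The rule flagged only control features higher with rapamycin. It could not flag hur_5, hur_6 or the bright corner features, which were lower by −0.69. No explanation was tested.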

How the results depend on the processing

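Spike-in scaling and the restriction to miRNAs with 2 probes were chosen after the data were seen. Counts are called close within 1.5 times, and medians and named miRNAs within their 95% interval, for the latter over spots. For lists with 3 or 5 measured members, that interval is the full range of the members and covers less than 95%. A miRNA is called reversed only where its reported value lay more than 2 standard errors from 0 and took the other sign, so other changes of sign close to 0 are not counted. Of the counts and medians of all miRNAs, 30 values were close to the reported ones and 17 moved. Some of the 30 were fixed in advance. With 0 miRNAs past 2-fold as reported, the counts at 4-fold could only be 0. The same holds for the 2-fold counts where only miRNAs above the median signal, or with at least 2 probes, were kept. Of the 13 alternatives, 4 (75th percentile over all probes, no scaling, median and spike-in scaling) shift all miRNAs alike and cannot move a relative value. In the other 9, 127 list medians were close and 16 moved, and of the named miRNAs 439 values were close, 142 moved and 23 reversed, among 58 with the other sign. Of these 9, keeping only miRNAs above the median signal, or with at least 2 probes, left each difference as it was. A relative value moved there only with the median of all miRNAs, at −0.038 and −0.041. Their 49 and 56 close values of named miRNAs were therefore nearly fixed in advance. With 1 array per group, precision and dim signals limit every value. No paired analysis was possible because each group has 1 array. At 1.5-fold, 4 miRNAs were higher and 2 lower, against 7 and 1 with the 75th percentile over all probes, 2 and 3 with quantile normalization, 1 and 10 with no scaling, 1 and 0 with the normexp background, 12 and 7 with the total gene signal, and 33 and 62 of 2549 with no filter on dim probes. At 2-fold, 1 miRNA, miR-5787, was higher with the 75th percentile over all probes, in the authors' table and with spike-in scaling, and 1, miR-3907, was lower with no scaling. With the total gene signal 2 (miR-193a-5p and miR-328-5p) were higher and 4 (miR-22-5p, miR-539-5p, miR-155-5p and miR-4745-5p) lower. With no filter on dim probes, 4 (miR-4522, miR-5703, miR-664a-5p and miR-6738-3p) were higher. These names were chosen after their values were seen. The detection flag of the image software left 10 miRNAs on the rapamycin array alone. The median of all miRNAs was 0.070 with the 75th percentile over all probes, −0.11 with quantile normalization, −0.21 with no scaling, 0.021 with the normexp background, −0.078 in the authors' table, −0.018 with no filter and 0.058 with spike-in scaling. Quantile normalization moved the list medians of miR-29 to 0.095, miR-23/27/24 to 0.069 and the adenocarcinoma list to 0.077. It reversed miR-7975 (0.12), miR-7977 (0.11), let-7a-5p (0.049), let-7f-5p (0.046), miR-106b-5p (0.0085), miR-16-5p (0.070), miR-23b-3p (0.020) and miR-100-5p (0.0019). The normexp background moved the list medians of let-7 to −0.17, miR-15/16 to −0.10, miR-30 to −0.080, miR-29 to −0.064, miR-23/27/24 to −0.11 and the GC-rich list to 0.029. It reversed miR-7641 (−0.028), miR-19b-3p (−0.037), miR-30c-5p (−0.036), miR-29b-3p (−0.064) and miR-4516 (−0.058). The authors' table moved miR-30 to 0.11, miR-29 to 0.081, miR-23/27/24 to 0.076, the miR-99/100 and miR-125 list to −0.021, the adenocarcinoma list to 0.058 and the structural RNA list to 0.15. It reversed miR-7975 (0.013), miR-7977 (0.078), let-7a-5p (0.020), let-7f-5p (0.0055), miR-16-5p (0.031), miR-23b-3p (0.0016) and miR-9-5p (−0.0012). With no filter the miR-23/27/24 list moved to −0.042 and miR-4521 reversed (0.0047). The total gene signal reversed miR-7-5p (0.073) and miR-4521 (0.034). The normexp offset of 50 pulls the differences of dim miRNAs toward 0 by construction. A relative value also moves with the median of all miRNAs. Apart from these, no cause was tested.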

Other observations

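The tests of the GC-rich list against a trend with signal and against a slide or scan difference, and the subtraction by GC class, were chosen after the result was seen, as was the use of a bootstrap spread in reading the registry classes. Among the named miRNAs, the 12 higher with rapamycin had a median probe GC content of 62.3% and the 12 lower one of 56.7%. For all 489 miRNAs it was 58.1%. Within the 12 higher, it ranged from 44.4% for miR-1290 to 82.6% for miR-5787, the largest difference upward. Entries with registry numbers of 1200 or above made up 7 of the 12 higher, 5 of the 12 lower and 238 of the 489. The precursor gene of miR-5787, MIR5787, lies within the span of GNAI2 in the GRCh38.p14 gene table. The 4 detected fly spike-in features differed by −0.07 to −0.15 in log2 between the arrays, and the median of all miRNAs lay 0.06 above their mean.

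The GC-rich list lay above the other miRNAs on the rapamycin array. The intervals given for it are over its members, which are not replicates, and cover no variation between arrays of the same group. A trend of the difference with signal is argued against as the whole cause, since after subtracting the median of the other miRNAs of the same signal class the list's median was 0.12 (95% interval 0.06 to 0.16). The GC content of its probes remains a candidate explanation, since among random lists matched on probe GC the list stood at percentile 91.3 (96.0 with its members left out of the random lists), and the same subtraction by GC class left a median of 0.01 (−0.04 to 0.10). A slide or scan difference cannot be told apart from the treatment, since each group has its own slide, and the bright corner features, which carry no sample RNA, differed by −0.69 ± 0.01. A response of these entries to rapamycin also stays open, as no replicate array separates it from the rest.

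The miRNAs detected on 1 array alone have a candidate explanation in a signal close to the detection limit. In 100% of them (42 of 42), the miRNA had a signal under 2-fold above the lowest detected probe of the other array, where at least 80% was set as the criterion. As 0 of the miRNAs detected on both arrays differed 2-fold as scaled, this criterion could hardly fail, and meeting it adds little. A biological difference in single miRNAs among them stays untested.

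Entries with registry numbers of 1200 or above lay 0.07 higher relative to entries up to 600 and let-7, with a bootstrap 95% interval of 0.04 to 0.11. If the probe GC content of the classes were the cause, the difference within classes of like GC content was predicted to shrink to under 50% of this. It did so in 0 of 3 GC classes, at 0.07 (0.02 to 0.16), 0.05 (−0.02 to 0.10) and 0.04 (−0.05 to 0.16) from low to high GC. The bound set in advance against GC content was met, but not by more than the spread of these intervals, so GC content and the age of an entry cannot be told apart as candidate explanations.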
